A study of Aedes albopictus with 6 samples.

How the data were processed

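Total RNA was taken from whole bodies of virgin females and males of the Foshan strain, with 3 biological replicates of 30 mosquitoes per sex, per the series design. Per the labels' protocols, ribosomal RNA was removed, linear RNA was digested with RNase R, directional libraries were made with a KAPA kit and paired reads were sequenced on a HiSeq X. The submitters' processing notes name Bowtie2 2.1.0. The circRNA caller, the genome build and the annotation are not given in the sources used here. Groups and replicate numbers were taken from the sample titles and the sex label.

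The deposited count table holds whole-number counts of back-splice junction reads per circRNA and library, not normalised, per the file headers and the values. It has 30393 lines, because a circRNA is repeated for each protein of its host gene with the same counts, and these lines were collapsed to 8690 circRNAs. Every circRNA listed had at least 2 reads in at least 1 library. The deposited table of CPM values, normalised by TMM by the authors as the title of the table says, holds 764 circRNAs, each with 18 or more reads in total. Multiplied by 1 factor per library, 100% of its values came out as the deposited counts within 0.01 reads, so whole reads were recovered and the factor gives an implied library total, TMM scaling included. The deposited spliced length per circRNA is the authors' value. Host gene, product name and junction type were taken from the count table.

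Contig positions are printed as the table gives them. Spliced length equals the end minus the start for 604 circRNAs and 1 base less for 836, so whether starts count from 0 or 1 was not settled. Reads without molecular identifiers are not independent molecules, so floors cover counting error only. A fold against a sex without reads was computed from the reads pooled over the libraries of the other sex, against 3 reads over the 3 libraries of that sex. Possible copies were circRNAs with the same span and spliced length at another host gene and either the same product name or an intron inside: 451 of the circRNAs listed and 2 of those called. This definition was widened after the data were seen. Opposite strands of the same position were listed for 64 circRNAs. Replicates differed by more than sampling noise (chi-square per degree of freedom 2.12 to 2.92 within a sex). Reads without molecular identifiers can exceed such noise even between repeat libraries, so this does not show separate replicates. All 6 libraries were kept as separate replicates because the series design gives them as biological replicates.

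Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with a minimum count of 5 and a minimum total of 15, dispersion estimates, and the quasi-likelihood F test of sex, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are female over male, and the SE is the size of the log2 fold change over the square root of F. Levels are counts per 10000 reads of the TMM-scaled library, as mean ± SD. Counts were also summed over the circRNAs of each host gene, leaving out circRNAs without one, and tested alike. Choice among circRNAs of a host gene used diffSpliceDGE with the Simes test. Numbers of circRNAs and reads per library were compared by an exact permutation test, with thinning to the smallest library as an exact expectation, and lengths by a permutation test with 100000 resamples. Figures were drawn with matplotlib in Python 3.11.15.

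A set of 15 gene lists was fixed from product names before the data were examined, as were the tests, the rule for named genes and most alternatives: muscle structure, neuronal signalling and synapse, axon guidance and cell adhesion, ovary and oogenesis, testis and sperm axoneme, small RNA pathway, sex determination, hormone and nutrient signalling, RNA binding and splicing, chromatin and transcription, cell cycle, immunity and hemocytes, chemosensation and vision, cuticle and trachea, and gut and metabolism. Lists with 5 or more tested host genes were tested with camera in limma 3.58.1 on log2 CPM, with the preset correlation of 0.01, with an estimated correlation, and with fry. Named circRNAs were, per direction, the 10 with the largest change and the 5 with the smallest p among called circRNAs whose libraries of the 2 sexes did not overlap; the 5 most abundant; up to 2 called host genes per direction and list; the 5 host genes with the smallest p for choice, with the circRNA at either extreme; and up to 5 circRNAs per sex found in that sex only, by reads.

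The edgeR tests of circRNAs and host genes, the choice test and the camera list test were tried on simulated data. The other tests were not. Counts were drawn from the real means and library sizes with 100 features changed by each fold size. Of 738 circRNAs, the test recovered 15% of those changed 2-fold and 59% of those changed 4-fold, with 3 false calls among 538 unchanged. Of 870 host genes, it recovered 17% and 68%, with 2 false calls among 670. The choice test recovered 17 of 30 host genes with 1 circRNA changed 8-fold among 75, with 0 false calls. The list test recovered the neuronal list, lowered 1.5-fold, among 9 lists. That was 1 draw with genes simulated independently, so it does not cover correlation between members. With these libraries most simulated 2-fold changes were therefore not recovered.

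The alternatives were size factors of DESeq2 1.42.0, upper quartile or no scaling; other filters; DESeq2's Wald test and limma-voom; limma on log2 of the deposited CPM with 1 or 0.1 added; the replicate number as a block; a fold threshold; other minimum read numbers; and leaving out each library in turn, with the tested features kept. Chosen after seeing the data were the implied library totals, the count test on reads recovered from the CPM table, exon-exon junctions alone, and leaving out circRNAs with a possible copy. The gene table of another assembly (AalbF5) was not used for positions. No genome sequence was used.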

Results

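Circular RNAs (circRNAs), closed transcripts made when a downstream splice site joins an upstream one, were profiled in whole bodies of the Asian tiger mosquito from the Foshan laboratory strain. Virgin females and males aged 2 days were compared, with 3 pools of 30 mosquitoes per sex. The comparison asks which circRNAs differ between the sexes before mating and blood feeding. The title of the series concerns ovary development and names circRNA-407 and Foxl. Neither name matched an identifier in the tables, so no value is given for them.

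The 6 libraries listed 8690 circRNAs from 4166 host genes, and 502 further entries of that total had no host gene. Exon-exon junctions made up 7156 of the circRNAs (82.4%), intron-intron junctions 533 and intergenic junctions 528. The median spliced length was 648 bases (quartiles 413 and 1009, over 7635 circRNAs with a length). Most host genes (2481) gave 1 circRNA, whereas 37 gave 10 or more. The zinc finger protein 420 gene (LOC109420654) gave 34, and dystonin (LOC109422269), a cytoskeletal linker, gave 30. In all, 3796 circRNAs had reads in 1 library and 862 had reads in all 6.

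Male libraries held more back-splice junction reads than female libraries, and more circRNAs, and at equal depth the difference in circRNAs with at least 2 reads was within the spread between replicates. Female replicates 1, 2 and 3 held 16792, 17197 and 13322 junction reads, and male replicates 1, 2 and 3 held 21624, 24852 and 27257. At least 2 reads were found for 2385 ± 222 circRNAs per female library and 3420 ± 212 per male library (SD, n = 3 each). After thinning each library to 13322 reads the numbers were 2141 ± 36.6 in females and 2164 ± 41.5 in males, a female minus male difference of -23.6 (exact permutation test, two-sided, p = 0.5). At a minimum of 5 reads the thinned numbers were 717 ± 42.4 and 635 ± 4.42 (difference 82.4, exact permutation p = 0.1). The difference in junction reads, -8807, had an exact permutation p = 0.1, the smallest that 3 against 3 libraries allow. Set against the TMM-scaled library totals implied by the authors' CPM table, junction reads summed to 1975 ± 67.3 CPM in females and 1978 ± 52.8 CPM in males (n = 3 each, exact permutation p = 0.9). TMM scaling itself evens out levels between libraries, so these sums cannot test whether circRNA content differs between the sexes.

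**Figure D1:**
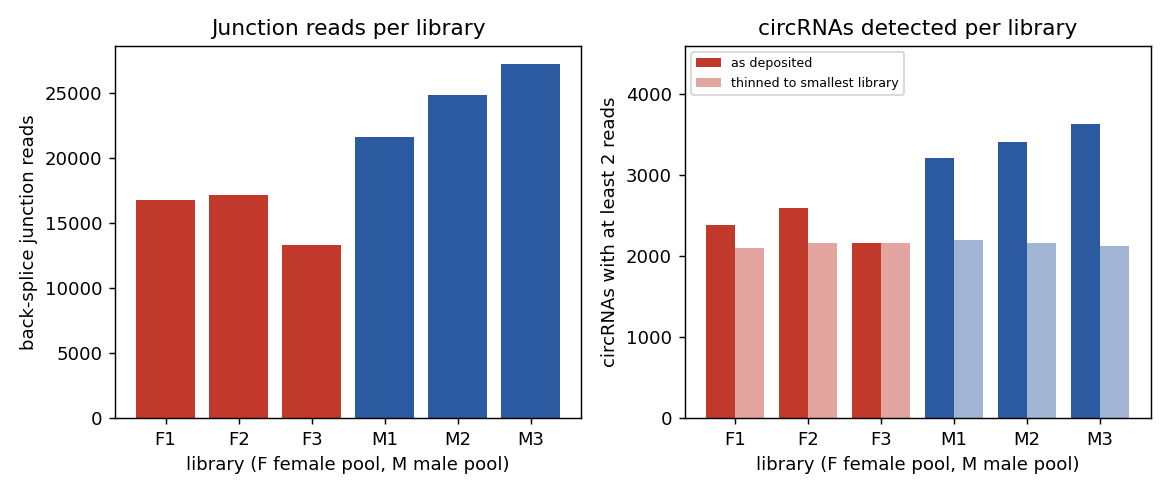
Back-splice junction reads per library (left) and circRNAs with at least 2 reads per library (right), as deposited and after thinning to the smallest library; red bars are female pools and blue bars male pools. Male libraries are deeper, with 21624 to 27257 junction reads, and at equal depth the 6 libraries lie between 2099 and 2207 circRNAs.

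In females, 28 circRNAs were higher than in males, among them products of a digestive protease gene, a clock gene and a basement membrane gene. An exon-exon circRNA of trypsin-1 (LOC109420035; contig NW_021838687.1, 72881492 to 72881762, minus strand), a serine protease that cleaves proteins in the gut, stood at 7.65 ± 1.42 normalised junction reads per 10000 in females and had no read in any male library (n = 3 each). That is at least 18.9-fold higher, against a floor of 3 reads over the 3 male libraries. All 9 circRNAs listed for trypsin-1 had an end inside a continuous block of another of them. An intron-intron circRNA of LOC115263426 (contig NW_021837623.1, 73540 to 75754, minus strand), a gene without a product name, stood at 16.4 ± 2.62 in females and 0.43 ± 0.47 in males, with 77 female reads and 3 male reads. An exon-exon circRNA of LOC109413956 (contig NW_021838153.1, 97090452 to 97091250, minus strand), which encodes an aryl hydrocarbon receptor nuclear translocator-like protein of the kind that drives the circadian clock, was 11.3-fold higher in females, at 6.69 ± 2.67 against 0.52 ± 0.55. Its 4 male reads make this fold imprecise: the log2 fold change was 3.49, and 4.56 without male replicate 3. This circRNA missed the threshold without female replicate 2 or 3 and without male replicate 1 or 2 (edgeR adjusted p from 0.0518 to 0.0697).

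Further circRNAs of single genes were higher in females. The circRNA of the perlecan-type basement membrane proteoglycan (LOC109404958) was 6.94-fold higher, with 8.80 ± 2.23 in females and 1.23 ± 0.15 in males. The circRNA of contactin-associated protein-like 4 (LOC109399283) was 5.28-fold higher. That of programmed cell death protein 4-like (LOC109408930), a repressor of translation, was 4.34-fold higher. That of the endoplasmic reticulum mannosidase that trims N-glycans (LOC109415549) was 4.22-fold higher. The uncharacterized genes LOC109406048, LOC109397236 and LOC115254075 gave circRNAs that were 7.35-fold, 5.97-fold and 3.78-fold higher. For LOC109397236 the log2 fold change was 2.58, and 3.79 without male replicate 3. Among abundant circRNAs, that of the long non-coding RNA LOC115256201 reached 97.6 ± 23.4 in females against 35.1 ± 2.60 in males, 2.78-fold higher. The circRNA of Rab-11B-like (LOC109415406), a small GTPase of recycling endosomes, stood at 43.4 ± 7.15 against 17.0 ± 2.69, and that of LOC109423355 at 54.3 ± 19.6 against 22.04 ± 7.61.

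In males, 21 circRNAs were higher than in females. The smallest p belonged to a circRNA of an RNA exonuclease gene, and the largest fitted changes to circRNAs of a synaptic protein, a phosphatase and a subunit of mitochondrial complex I. The exon-exon circRNA of RNA exonuclease 1 homolog (LOC109431460; contig NW_021837156.1, 56098347 to 56098626, plus strand) stood at 46.8 ± 6.08 in males and 7.93 ± 0.90 in females, a log2 fold change of female over male of -2.56 (5.89-fold higher in males). An exon-exon circRNA of the synapse-associated protein gene LOC109417341 (contig NW_021838723.1, 259250 to 267872, plus strand) had no read in females and 5.42 ± 1.92 in males. Its 41 reads pooled over the male libraries were at least 8.69-fold higher than a floor of 3 reads over the 3 female libraries. An exon-exon circRNA of dual specificity protein phosphatase 3 (LOC109402145; contig NW_021837378.1, 20520128 to 20531045, plus strand), which acts on MAP kinases, had 1 female read against 50 male reads, 0.24 ± 0.42 against 6.79 ± 2.08. The circRNA of the 55 kDa regulatory subunit of phosphatase PP2A (LOC109400400) was 7.54-fold higher in males, with a log2 fold change of -2.91 that was -4.45 without female replicate 1 and -2.31 without female replicate 2. An uncharacterized gene (LOC115259546) listed a circRNA of the same span and spliced length with 1 female and 24 male reads, so the split of reads between these genes is uncertain.

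Further male-higher circRNAs came from NADH dehydrogenase flavoprotein 2 (LOC109416331), a subunit of mitochondrial complex I, with 1 female and 43 male reads, and from target of Myb protein 1 (LOC109420220), an endosomal sorting protein, at 24.99 ± 1.71 in males and 5.48 ± 4.07 in females. The circRNA of leucine-rich repeat flightless-interacting protein 2 (LOC109402218) was 5.74-fold higher in males. The uncharacterized genes LOC109427367, LOC109419083 and LOC115262158 gave circRNAs that were 5.55-fold, 4.76-fold and 4.47-fold higher. Without female replicate 3 the log2 fold change of LOC109419083 moved from -2.25 to -3.10, and without female replicate 2 that of target of Myb protein 1 moved from -2.17 to -2.86. An intergenic circRNA on contig NW_021838925.1 (positions 114126 to 114445, plus strand) stood at 42.5 ± 8.04 in males and 15.1 ± 5.99 in females.

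**Figure D2:**
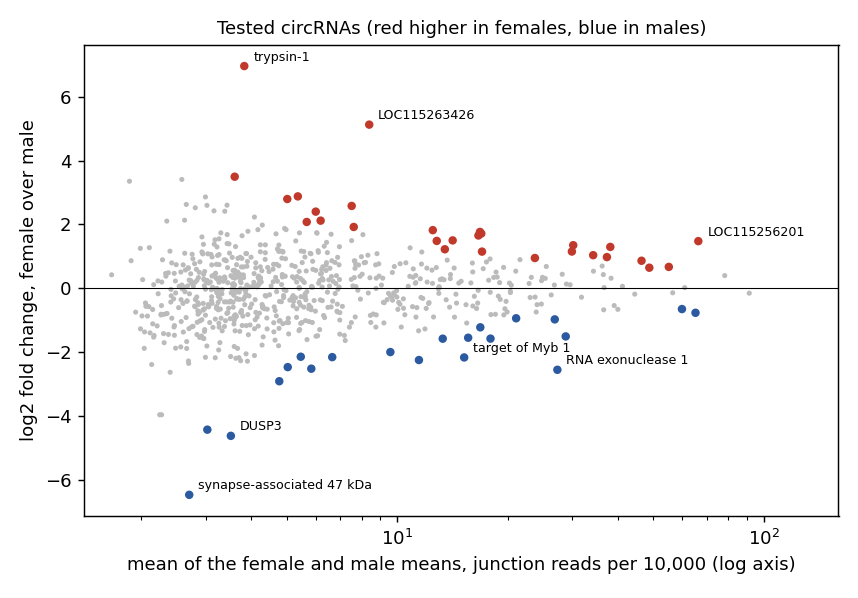
Log2 fold change of female over male (vertical axis) against the mean level in normalised junction reads per 10000 (horizontal log axis) for the 738 tested circRNAs; red points are the 28 higher in females, blue points the 21 higher in males and grey points did not pass. Fitted values of circRNAs with no read in one sex, such as trypsin-1, depend on a small added count.

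The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 738 circRNAs, which held 58.4% of the junction reads. Adjusted p was 1.7e-09 for RNA exonuclease 1 homolog (SE of the log2 fold change 0.30), 1.9e-08 for LOC115256201 (log2 fold change 1.48, SE 0.19), 2.4e-07 for LOC115263426 (5.13, SE 0.72, and 6.02 without male replicate 1), 9.5e-05 for trypsin-1 (SE 1.24) and 0.0028 for the synapse-associated protein (SE 1.51). In all 49 called circRNAs the 3 libraries of one sex lay above the 3 of the other, as did 26.96% of all tested circRNAs against the 10% that chance gives. Without male replicate 1 the calls fell to 14 and 8, and without male replicate 2 to 16 and 9. Of the 26 called circRNAs named in this comparison and the next ones, 12 passed in all 6 fits that left out 1 library: those of trypsin-1, LOC115263426, LOC109404958, LOC115256201, LOC109423355, LOC109415406, LOC109417786, LOC109431460, LOC109419083, LOC109420220, LOC109406888 and the intergenic circRNA. Of these, 8 passed under all alternatives, whereas LOC109404958, LOC109423355, LOC109415406 and LOC109417786 missed the threshold without a filter on low counts (adjusted p = 0.163, 0.0795, 0.118 and 0.0821, the highest over their alternatives). The other 14 each missed the threshold without at least 1 library, and their highest adjusted p over all alternatives ran from 0.0528 for dual specificity protein phosphatase 3 (without male replicate 1) to 0.538 for the mannosidase. Without a filter on low counts, 3 circRNAs were higher in females and 19 in males.

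**Figure D3:**
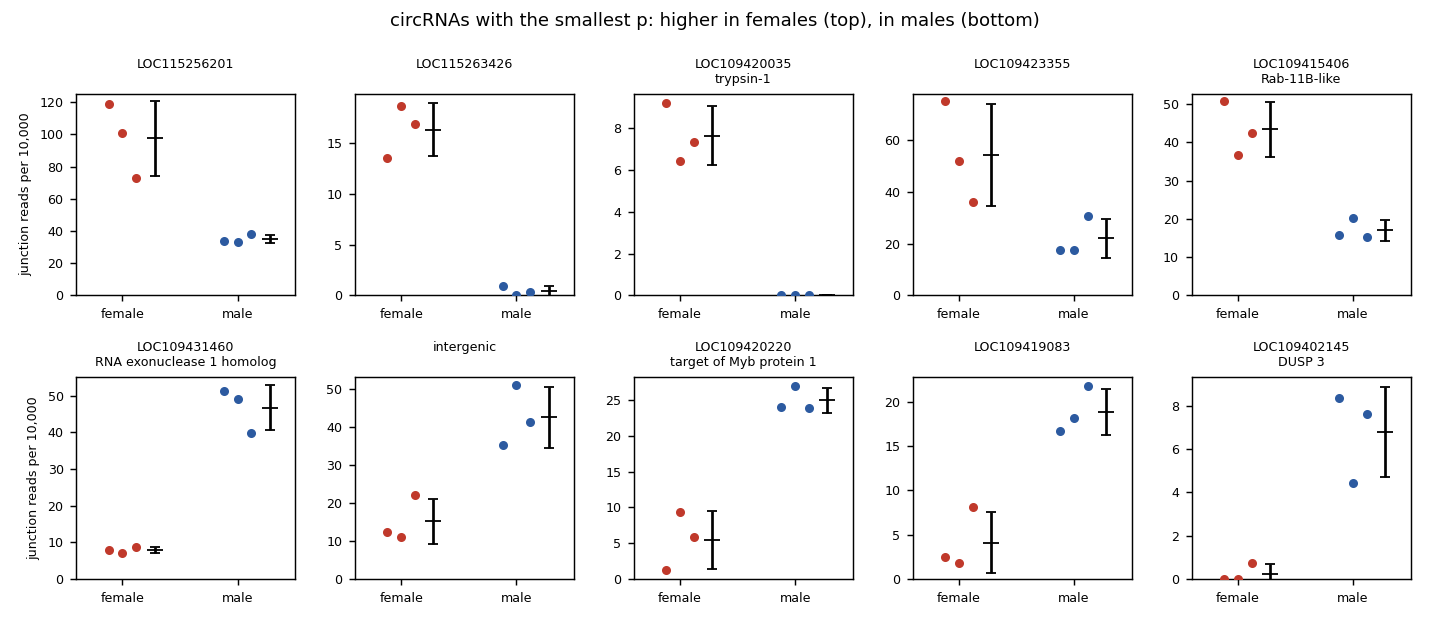
Normalised junction reads per 10000 in each library for the 5 circRNAs with the smallest p in each direction; points are libraries, and the bar beside them is the mean with its SD (n = 3). RNA exonuclease 1 homolog stands at 7.93 ± 0.90 in females and 46.8 ± 6.08 in males.

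The most abundant circRNAs came from LOC109412837, an uncharacterized gene, from tyrosine-protein phosphatase non-receptor type 21 (LOC109416253), from LOC115256201 and LOC109406888, and from cytospin-A (LOC109406300), a cytoskeletal organiser. The LOC109412837 circRNA stood at 86.5 ± 10.8 in females and 96.2 ± 10.5 in males (edgeR adjusted p = 0.63), and the phosphatase circRNA at 88.9 ± 5.56 and 67.6 ± 8.37 (adjusted p = 0.14, range over alternatives 0.040 to 0.81). Cytospin-A, which also had a possible copy, stood at 61.2 ± 11 and 60.6 ± 8.33 (adjusted p = 0.97). The LOC109406888 circRNA was higher in males, at 82.2 ± 1.21 against 48.1 ± 3.57 (log2 fold change -0.77, SE 0.18, edgeR adjusted p = 0.0027). A circRNA of the same span (649 bases) and spliced length (570 bases) was listed for LOC109404443, with 147 female and 367 male reads, so the split of reads between these genes is uncertain.

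Junction reads summed over each host gene showed 22 genes higher in females and 20 higher in males of 870 tested. In females the group of gut and metabolism genes held 2 of them: trypsin-1, at 16.4 ± 4.99 against 0.13 ± 0.22 reads per 10000, and the trehalose transporter Tret1-like (LOC109428485), which carries the blood sugar of insects across membranes, at 55.4 ± 10.4 against 27.4 ± 6.17. Hormone and nutrient signalling genes went both ways. Ribosomal protein S6 kinase beta-2 (LOC109418942), an effector of the nutrient sensor TOR, was 3.47-fold higher in females (log2 fold change 1.80, and 2.46 without male replicate 2), whereas diuretic hormone receptor (LOC109419645) and diuretic hormone receptor-like (LOC109420199), receptors for peptides that control fluid secretion, were 1.64-fold and 2.58-fold higher in males.

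Single members of other groups were higher in females: the histone methyltransferase trithorax (LOC109416761) among chromatin genes, at 25.8 ± 5.08 against 8.48 ± 3.72; the splicing regulator Nova-1-like (LOC109405447) among RNA-binding genes, at 75.2 ± 8.35 against 44.6 ± 1.95; and contactin-associated protein-like 4 among adhesion genes, at 19.9 ± 7.64 against 5.41 ± 2.40. Adjusted p by edgeR was 3.5e-06 for trypsin-1, 0.0068 for Tret1-like and trithorax, 0.0075 for diuretic hormone receptor-like and contactin-associated protein-like 4, and 0.012 to 0.013 for the other host genes of these groups. Of the 9 host genes named from the lists, only trypsin-1 passed in all 6 fits that left out 1 library. Without male replicate 1 the host gene calls were 11 in females and 9 in males, and without male replicate 2 they were 7 and 5. The groups held 9 of the 42 called host genes, and 33 belonged to none of the 15 lists. Of the 42, 35 also had a called circRNA, so most host gene calls rest on reads already tested singly. Trithorax and ribosomal protein S6 kinase beta-2 listed 1 circRNA each.

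Host genes of the neuronal signalling and synapse list had lower values in females. Of 36 tested members, 28 had a log2 fold change of female over male under 0, and the median was -0.64. Members were picked by words in product names, and the matching missed names that begin with synapse, such as that of LOC109417341. It took in a voltage-dependent anion-selective channel-like gene (LOC109433076, log2 fold change 1.27). The list is therefore no full measure of synaptic genes. By camera with its preset correlation the list had p = 0.0019 (adjusted p = 0.017 over 9 lists), but adjusted p = 0.21 with an estimated correlation. It passed fry's test for a shift in one direction (adjusted p of 0.00032, n = 36 members). Whether the list passed thus depended on the list test and its setting. The voltage-gated potassium channel subunit beta-2 gene (LOC109411905) was the member that passed the test, at 36.1 ± 6.86 reads per 10000 in females and 60.9 ± 7.28 in males (log2 fold change -0.76, SE 0.21, edgeR adjusted p = 0.027, and 0.0041 to 0.18 over its alternatives), and it missed the threshold without female replicate 1 or 2 and without male replicate 1 or 2. The other 35 did not pass, among them a metabotropic glutamate receptor 1-like gene (LOC109410169; 0.26 ± 0.45 against 4.52 ± 2.01), the calcium-activated potassium channel slowpoke (LOC109398458; 20.04 ± 7.49 against 34.5 ± 1.15) and neuroligin-3 (LOC109411553; 7.82 ± 4.43 against 16.8 ± 3.25). Adjusted over the list alone, 0 members were higher in females and 1 in males. Without female replicate 2 the list's adjusted p by camera was 0.070, and over all camera fits of the neuronal list median log2 fold change it ran from 0.0126 to 0.395.

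The other 8 tested lists did not pass camera, nor fry's test for a shift in one direction (adjusted p from 0.24 to 0.90). Their medians were -0.81 for muscle structure (9 genes, adjusted p = 0.71), -0.69 for axon guidance and cell adhesion (13, 0.88), -0.19 for hormone and nutrient signalling (14, 0.88), -0.04 for RNA binding and splicing (8, 0.88), -0.06 for chromatin and transcription (22, 0.97), -0.15 for immunity and hemocytes (5, 0.93), -1.09 for chemosensation and vision (5, 0.47) and 0.03 for gut and metabolism (18, 0.71). In RNA binding and in chromatin the camera direction was up although the median was under 0. Fry's mixed test, for changes in either direction, gave low unadjusted p in most of these lists. By this mixed test p was 0.0011 for gut, 0.0020 for hormone, 0.0036 for chromatin and 0.0042 for RNA binding. For chemosensation it was 0.0083, for adhesion 0.012, for muscle 0.045 and for immunity 0.80. Adjusted over the list alone, 2 gut genes, 1 RNA-binding gene, 1 chromatin gene, 1 adhesion gene and 1 hormone gene were higher in females and 3 hormone genes were higher in males; no muscle, immunity or chemosensation gene passed.

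**Figure D4:**
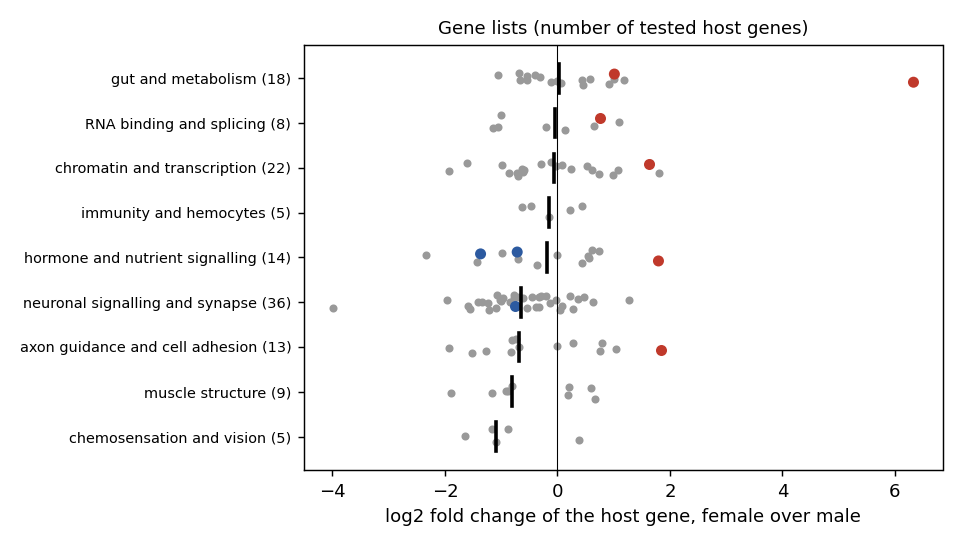
Log2 fold change of female over male for the tested host genes of each list with 5 or more; each point is a host gene, coloured points passed the test (red higher in females, blue in males) and the black bar is the median. The neuronal list has 28 of 36 members under 0 and a median of -0.64.

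The lists of germ line and sex determination genes held few tested host genes, and none of these passed the edgeR test. In the ovary list, encore (LOC109426825), a protein of egg chamber development, stood at 5.88 ± 5.14 in females and 1.67 ± 0.96 in males, and maternal protein pumilio-like (LOC109409584) at 6.57 ± 4.47 and 5.06 ± 2.74. In the testis list, boule-like (LOC109426659), an RNA-binding protein of meiosis, stood at 9.54 ± 2.25 in females and 5.69 ± 2.06 in males, and tubulin beta chain-like (LOC109424852) at 2.02 ± 1.75 and 4.73 ± 1.07. In the sex determination list, the 2 tested genes were both sex-lethal-like, so the list is no measure of sex determination as such. These genes, LOC109404970 and LOC115261543, stood at 12.5 ± 1.31 and 12.1 ± 3.29 in females and at 17.7 ± 5.70 and 16.1 ± 4.70 in males. In the small RNA pathway, 3 argonaute-2 genes had log2 fold changes from -0.61 to 0.44. The cell cycle list had a median of -0.08, but its 4 genes were all cyclin-T-like or kinesin-like genes picked by those words in their names. It is therefore no measure of the cell cycle as such. The cuticle and trachea list (4 genes, all mucins) had a median of -0.31. Lists with fewer than 5 tested genes were not given a list test.

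Choice among the circRNAs of a host gene did not pass edgeR's Simes test between the sexes in any of 75 host genes with 2 or more tested circRNAs. The lowest p belonged to the G(q) alpha subunit gene (LOC109417786), which couples receptors to phospholipase C. There, one circRNA was higher in females, at 26.1 ± 7.25 against 7.85 ± 2.02, and another stood at 1.63 ± 1.15 in females and 4.34 ± 2.30 in males. In the perlecan-type gene LOC109404958, the circRNA from 51362918 to 51363462 on contig NW_021837267.1 was the one described above, and that from 51345951 to 51363221 stood at 2.56 ± 0.63 in females and 4.72 ± 1.92 in males. In the C-1-tetrahydrofolate synthase gene (LOC109411581), an enzyme of folate metabolism, the circRNA from 1903280 to 1904068 stood at 37.1 ± 5.53 and 36.4 ± 13.2, whereas the one from 1897382 to 1904068 had 1 female and 32 male reads. In LOC109406048 the extremes were 9.46 ± 3.30 against 1.25 ± 0.83 and 2.52 ± 0.36 against 2.90 ± 1.94. In zinc finger protein 420 they were 44.7 ± 7.83 against 27.8 ± 7.23 and 0.58 ± 1.01 against 4.22 ± 0.94. Tested singly, both of these zinc finger circRNAs and the longer C-1-tetrahydrofolate synthase circRNA passed with 1 library left out: the first without female replicate 3 (edgeR adjusted p = 0.0367), the second without female replicate 2 (0.037) and the third without female replicate 3 (0.0386). For the second and the third, leaving out that library removed every female read. Without female replicate 2 the log2 fold change of the second G(q) alpha circRNA moved from -1.35 to -2.07, and it did not pass.

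By edgeR's Simes test the count of host genes with a sex-dependent choice was 0 at an adjusted p of 0.05 (lowest adjusted p 0.30) and 5 at an unadjusted p under 0.05. The gene-level F test called 1, the perlecan-type gene LOC109404958 (adjusted p = 0.015), and 11 at an unadjusted p under 0.05. Leaving out female replicate 2 gave 2 host genes.

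With at least 2 reads in all 3 libraries of one sex and no read in the other, 8 circRNAs were found in females only and 86 in males only. The females-only circRNAs with most reads were those of trypsin-1 (36 reads), the mitochondrial carrier protein Rim2-like (LOC109423917; 20 reads), LOC109411545 (14), inositol monophosphatase 3 (LOC109412116; 10, with a possible copy) and the ubiquitin ligase UBR1 (LOC109405489; 10). The males-only circRNAs with most reads were those of the synapse-associated protein LOC109417341 (41 reads), LOC115253688 (25), myrosinase 1-like (LOC109398100; 25), dachshund homolog 2-like (LOC109429783; 23), a transcriptional regulator of eye and leg development in insects, and alpha-mannosidase 2-like (LOC109401057; 23).

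The libraries differed in depth. A floor of 3 reads corresponds to 0.41 reads per 10000 over the male libraries and 0.64 over the female libraries. After thinning all libraries to the smallest, the expected numbers were 11.8 in females only and 28.6 in males only. Leaving out 1 library eases the rule for its sex to 2 libraries, and the thinned numbers were then 39.65 to 41.57 in females only and 46.85 to 58.34 in males only without a female library, and 19.08 to 26.75 and 73.41 to 77.41 without a male library. Without thinning, the circRNAs detected in females only numbered 31, 28 and 33 without female replicates 1, 2 and 3, and 15, 12 and 21 without male replicates 1, 2 and 3. The circRNAs detected in males only numbered 130, 169 and 134 without female replicates 1, 2 and 3, and 209, 213 and 184 without male replicates 1, 2 and 3.

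The circRNAs higher in females and those higher in males did not differ detectably in length. Their median genomic spans were 749 bases (28 circRNAs) and 934 bases (21 circRNAs), a difference in log10 span of -0.096 (permutation test, two-sided, p = 0.45). Median spliced lengths were 496 bases (27) and 574 bases (20), with a permutation p = 0.32. CircRNAs were the units here and are not independent replicates. The length of sex-biased circRNAs differed by 4.9e-05 in log10 span without male replicate 2 and by 0.094 without male replicate 3.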

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

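The alternatives chosen after seeing the data were the implied library totals, the count test on recovered reads, exon-exon junctions alone and the removal of possible copies. No called circRNA or host gene changed sign under any alternative that refitted the counts, leave-one-out fits included. Scaling changed little: 47 to 48 of the 49 called circRNAs stayed called under the other scalings, and the count test on recovered reads called 26 circRNAs higher in females and 21 in males of 764. Filters mattered more. Requiring 2 reads in 3 libraries gave 14 circRNAs higher in females of 2222 tested, and no filter gave 3 of 8690, with 13 host genes higher in females, and 34 and 22 of the 49 circRNAs stayed called. The loss was mostly on the female side, and the median log2 fold change of the circRNAs tested moved from -0.01 to -0.26 and -0.88. The cause of this was not tested. DESeq2 called 35 host genes higher in females, and limma on log2(CPM + 1) called 36 circRNAs higher in males; the cause was not tested. Leaving out 1 library gave 14 to 27 circRNAs and 7 to 26 host genes higher in females, and 8 to 30 circRNAs and 5 to 25 host genes higher in males. The lowest numbers came without male replicate 1 or 2, and the cause was not tested.

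The number of lists that differed was 0 with the estimated correlation, the default filter (fewer genes tested) and circRNAs as units, and 0 to 1 with a library left out. The median of the neuronal list then was -0.64 (adjusted p = 0.21), -0.58 (0.39) and -0.61 (0.076), and -0.85 to -0.63 with a library left out. Sex-dependent choice was called for 1 host gene by the gene-level F test and for 0 to 2 with a library left out. With at least 1 read, circRNAs detected in females only numbered 15 and circRNAs detected in males only 243, and with at least 5 reads 1 and 8. Thinning gave 11.8 in females only and 28.6 in males only. Leaving out 1 library gave 12 to 33 and 130 to 213 without thinning, and 19.08 to 41.57 and 46.85 to 77.41 with it. The female minus male difference in circRNAs per library was 82.4 at 5 reads, for which the cause was not tested, and -1035 without thinning, at unequal depth. At 1 read it was -731.3, which is no comparison at equal depth: the table lists only circRNAs with at least 2 reads in a library, so deeper libraries keep more circRNAs at 1 read after thinning. Over the circRNAs of the CPM table the difference in junction reads was -5128, since fewer reads enter. The difference in log10 span was 0.039 with 2 reads in 3 libraries and -0.23 to 0.094 with a library left out; the cause was not tested.

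Replicates of the sexes share only a number: deviations of same-numbered libraries correlated at 0.025, 0.0034 and -0.020 across circRNAs and no library correlated best with the library of its own number. With the replicate number as a block, 28 circRNAs were higher in females and 21 in males, host gene calls were 28 and 24, the neuronal list had a median of -0.79 and choice gave 0 host genes. Of 561 refits of the 26 called circRNAs named, 52 lost the threshold, 33 of them with a library left out; of 153 refits of 9 host genes, 21 did.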

Other observations

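The host genes named outside the fixed lists, the test of junction ends in trypsin-1 and the balanced fits and split ratios for presence in one sex were chosen after the values were seen; so were the further conditions noted for the neuronal and trypsin-1 tests. The NMDA glutamate receptor subunit 1 gene (LOC109401442), a synaptic receptor outside the neuronal list, stood at 32.4 ± 0.15 reads per 10000 in males and 12.8 ± 1.82 in females (n = 3 each, edgeR adjusted p = 0.0057). Adenylate cyclase type 2-like (LOC109418769) was 2.46-fold higher in males and a cAMP-specific phosphodiesterase (LOC109427728) 3.10-fold higher (adjusted p = 0.013 and 0.0068), whereas the phosphodiesterase 8-like gene LOC109425721 (log2 fold change 0.19) and the phosphodiesterase 11-like gene LOC109397513 (0.67) did not pass. The sodium/hydrogen exchanger 9B2 gene (LOC109411550) was 3.26-fold higher in males. In females, the lipid storage droplet protein gene LOC109413900 was 2.78-fold higher (adjusted p = 0.024).

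The sexes gave 49 called circRNAs and 42 called host genes, and the highest number in any other of the 10 splits of the 6 libraries into 3 and 3 was 0 for each. For gene lists the real value was 1 and the highest other 0, and for choice of circRNA both were 0. The 10 splits are too few for a share under 0.05. For presence in one sex alone, the sexes gave 94 circRNAs and the other splits 17 to 30, at unequal depth. After thinning to the smallest library the expected totals were 40.4 for the sexes and 9.8 to 15.9 for the other splits.

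The other circRNAs of a host gene tended to lie on the side of its called circRNA. This was tested in 22 host genes whose uncalled circRNAs had 20 or more reads, and in 17 of them (77.3%, 95% exact binomial interval 54.6 to 92.2) the summed rest lay on the same side (exact binomial p = 0.017). A candidate explanation is a sex bias of the host gene, for example in its transcription; linear transcripts were not measured. Exceptions were the perlecan-type gene LOC109404958, G(q) alpha, REST corepressor (LOC109411230), cytospin-A-like (LOC115253606) and LOC109404436.

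The neuronal list had a lower median in females. Low abundance at unequal depth was tested against 10000 random lists matched on mean expression, and the median of the list lay at percentile 0.15. The random lists were drawn gene by gene and leave out correlation between members, which took the adjusted p by camera from 0.017 to 0.21. The percentile may therefore be too extreme, and it cannot by itself exclude depth and abundance. A smaller share of nervous tissue in female pools that lowers all members alike was tested by their spread, which exceeded their errors at Cochran's Q over n = 36 members (p = 0.0387), a value first set to exclude it. That bound proved too weak, since removal of any of 6 members took p above 0.05 (0.173 without neuroligin-4-like LOC109427198), so a smaller tissue share cannot be told apart from gene-by-gene differences. Sex differences in the neurons themselves were not tested.

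More circRNAs were seen in males only than in females only, 86 against 8. Deeper male libraries could give such a gap, and thinning to the smallest library took the ratio from 10.8 to 2.42. With 1 library of each sex left out, which keeps the rule equal for both, the thinned ratio was 1.52 to 2.11 in the 9 fits. However, the larger over the smaller number reached 2.61 in 1 of the other splits of the libraries (female replicates 1 and 3 with male replicate 1), so whether depth is the whole cause cannot be told apart from the spread between libraries. Female libraries also resembled each other less, with a mean correlation across circRNAs of 0.54 after thinning, against 0.65 in males, and a circRNA must appear in all 3 libraries to count.

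All 9 circRNAs of trypsin-1 were almost confined to females, with 77 female reads, 1 male read and 12 distinct ends. Chimeric cDNA made from an abundant linear mRNA would leave ends off the splice sites. In 9 of 9 of these circRNAs an end lay inside a continuous block of another circRNA of the gene, percentile 99 among 297 other host genes with 5 or more circRNAs, whose median share was 0%. These junctions may trace the linear trypsin transcript of females, but the values cannot decide between that and circles. No annotated splice sites were compared, and the test was chosen after the values were seen. The 9 circRNAs also lay close together, between positions 72881061 and 72881987, and the other host genes were not matched for length. CircRNAs packed into a short stretch can have ends inside each other's blocks whatever their origin, so the percentile cannot decide. Linear RNA had been digested with RNase R, and 1 junction recurred in the 3 female libraries with 15, 11 and 10 reads. Reads shared with a near-identical trypsin gene stay open: 0 circRNAs of another host gene had the same span, spliced length and product name, which was first set to exclude sharing, but a copy without listed circRNAs would leave none, and 5 other trypsin genes held 6 female and 18 male reads, too few to decide; a sex difference in true circles was not tested.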
